A study of Mus musculus with 12 samples.

How the data were processed

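RNA from KH2 mouse embryonic stem cells was measured on Affymetrix mouse expression arrays. Per the labels' protocols, cells were grown on feeders, treated with 0.3 µM RA in a differentiation medium for 2, 4 or 6 h or left untreated, replated on gelatin for 30 min, and 200 ng of RNA was labelled with biotin. The 12 arrays were placed in 4 groups of 3 from their labels, and all 12 were used. The deposited values are log2 signal for 45101 probe sets per array, per the labels, and the submitters' processing notes list limma 3.4.3. They do not state the method of normalization. On each array the deposited log2 values had a median between 6.05 and 6.10. No further normalization was applied before the tests.

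Probe sets were named with the platform's annotation: 34958 were assigned to 1 gene, 932 to several and 9211 to none. The arrays carry 64 control probe sets. Names of 34754 were matched to a mouse gene table by gene identifier, and no symbol needed updating. Probe sets of several genes were left out, and for each of the 18194 genes the probe set with the highest mean over all arrays was used. Some genes of the lists had no probe set named for them alone and were not analysed here.

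Group means of the 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.78 prior degrees of freedom), and each RA time was compared with no RA and with the other RA times. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each comparison, and the F test asked for any change over the 4 groups. Values are log2 differences of group means with the standard error (SE) of the fit unless SD is stated. The 31 gene lists, the rule for named genes, the comparisons and the alternatives were fixed before the data were examined. The lists hold 445 measured genes and were tested with camera at its preset inter-gene correlation of 0.01, with p-values adjusted over the lists. Members of a list were also adjusted over the list alone.

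The lists cover RA metabolism and receptors, the Hoxa, Hoxb, Hoxc and Hoxd clusters, Hox paralogue groups 1 to 5 and 9 to 13, Hox cofactors and Cdx genes, hindbrain and neural plate regulators, neurogenesis, naive pluripotency, primed epiblast, LIF and STAT3 targets, primitive endoderm, primitive streak and mesoderm, trophoblast, immediate early genes, feeder fibroblast markers, cholesterol synthesis, mitosis and G2/M, p53 targets, heat shock, unfolded protein and amino acid stress, hypoxia and glycolysis, Wnt targets, FGF and ERK feedback, Nodal and BMP targets, the super elongation complex, Polycomb and DNA methylation, meiosis and germ line, and the two-cell-like state. The rule for named genes took the 8 largest rises and falls against no RA at each time, the 5 largest between RA times, all with no overlap between the arrays compared, then up to 4 called members of each list per comparison against no RA (the members with the largest changes where fewer than 2 were called), and a fixed set of RA, Hox, pluripotency and other genes, 194 genes in all. Genes outside it are said to be chosen after their values were seen.

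The fits were tested on simulated data for 18194 genes with 200 changed. At a log2 change of 0.5, 68.7%, 77.6% and 79.1% of changed genes were recovered for 2, 4 and 6 h against no RA, and at a log2 change of 1, 98.5%, 97.0% and 100%, with 11, 8 and 9 false calls. A simulated shifted list passed camera and an unshifted list did not. The simulated noise was normal, independent between genes and of equal spread in all groups. In the data the untreated arrays deviated more from their group mean (SD across genes 0.130 to 0.197) than the RA arrays (0.0816 to 0.106). More genes were called in the data than were changed in the simulation (489, 4893 and 5409 at 2, 4 and 6 h against no RA). The Benjamini-Hochberg cutoff depends on the share of genes changed. For these reasons, recovery and false calls in the data may differ from those simulated. The alternatives were quantile normalization, median centring, the mean of a gene's probe sets, every probe set, probe sets without a cross-hybridization suffix, a filter on dim genes, a trended and robust variance model, array weights, fits of only the groups compared, replicate letter as a block, other thresholds, camera with an estimated correlation, fry (which tests a list against no change, where camera tests it against the other genes), and leaving out each array. The fry p-values given are those for a shift in a common direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6.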

Results

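Gene expression was measured in KH2 cells, a mouse embryonic stem cell line grown on feeder cells, before and during the first hours of exposure to retinoic acid (RA), the vitamin A derivative that binds the nuclear RA receptors and starts differentiation of these cells. The 12 arrays form 4 groups of 3 replicates, named A, B and C: no RA, and 2, 4 or 6 h in a differentiation medium with 0.3 µM RA. The treated cells received that medium together with RA, and nothing in the labels says that the untreated cells did, so each comparison against no RA holds the effect of both. The protocols differ on which cells were collected: the extraction text says that attached cells were kept after replating on gelatin for 30 min, while the treatment text reads as if the medium with unattached cells was spun down. Each array gave log2 values with medians between 6.05 and 6.10, and 18194 genes could be tested. The labels do not say whether replicates were separate cultures, so the p-values below measure the spread between these samples, which may be technical, and 3 arrays per group limit the precision of every value.

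Untreated replicate C stood apart from replicates A and B. Its correlation with them over all probe sets was 0.993, against 0.997 between A and B and 0.997 to 0.998 within the RA groups. Feeder fibroblast markers were lower in it, by a median of 0.50 on the log2 scale over 30 genes, and 24 of the 30 lay below the mean of A and B. As a list, these markers shifted up at 2 and 4 h against no RA (median 0.23 and 0.26) and not at 6 h (median 0.15), with adjusted p = 0.0385, 0.0472 and 0.576 by camera, and adjusted p = 0.687, 0.699 and 0.867 with an estimated correlation. Among single genes, 0, 5 and 2 of the 30 measured members were higher at 2, 4 and 6 h and 0, 2 and 3 were lower. Adjusted over the list alone, the numbers were 0, 5 and 2 higher and 0, 2 and 3 lower. At an unadjusted p under 0.05, 7 of them passed at 2 h. Without untreated replicate C, a comparison chosen after seeing the data, the list's camera test gave adjusted p = 0.852 at 2 h, 0.738 at 4 h and 0.278 at 6 h. Without untreated replicate A it gave 0.0709, 0.078 and 0.642. Without B the list shifted up at every time (adjusted p = 4e-07, 4.06e-05 and 0.0156), with 9, 17 and 11 members higher, so this shift depended on each untreated array. The call was also lost with the dim filter at 4 h (adjusted p = 0.0911). The fry test asks whether members moved in a common direction against no change, and not whether they moved more than other genes. Its adjusted p was 0.482 and 0.278 at 2 and 4 h. The gene lists below were likewise refitted without each untreated array, and not without each RA array. Col1a1, which encodes a type I collagen chain, did not pass at any time (0.14 ± 0.17, 0.26 ± 0.17 and 0.18 ± 0.17, SE).

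The first comparison asked which genes had changed after 2 h in RA. Cyp26a1, the enzyme that degrades RA, rose most, from 5.81 ± 0.16 to 11.92 ± 0.13 (SD, n = 3, log2 difference 6.11 ± 0.084 (SE, adjusted p = 9.85e-13)). Its untreated values lay under 6.07, the median of all deposited values, as did those of Hoxb1 and Tal2. Values under that median were not tested against background, so no fold is given for such genes here or below, and their log2 differences and places in a ranking hold for the deposited values alone. It was followed by Tal2, a basic helix-loop-helix factor (3.06 ± 0.20), the hindbrain homeobox gene Hoxb1 (2.93 ± 0.17), the glutathione-degrading enzyme Chac1 (2.86 ± 0.17), the lipid droplet protein Cidea (2.83 ± 0.14) and the posterior homeobox gene Cdx1 (2.61 ± 0.13). Camk2n1 (2.53 ± 0.28), an inhibitor of CaM kinase II, and the aquaporin Aqp3 (2.26 ± 0.087) completed the 8 largest rises. The falls were smaller. They were led by the neural factor Olig2 (by 1.29 ± 0.12), Gdap10 (by 1.24 ± 0.10), the heparan sulfate sulfotransferase Hs3st3b1 (by 1.12 ± 0.11), the anterior homeobox gene Otx2 (by 1.06 ± 0.18) and the transcription factor Jun (by 1.00 ± 0.14), and then by Fgf18 (by 0.97 ± 0.20), Zfp608 (by 0.94 ± 0.11) and Gcnt2 (by 0.93 ± 0.11).

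In all, 273 genes were higher and 216 lower at 2 h (limma, adjusted p under 0.05), and 46 of the first and 4 of the second differed by at least 2-fold. All 489 had no overlap between the 3 RA and the 3 untreated arrays, as did 22.2% of all genes, where chance gives 10%. After quantile normalization the split was 297 higher and 143 lower. The total was 229, 219 or 241 without RA 2 h replicate A, B or C, and 734 without untreated replicate C, and of these 225, 216, 233 and 406 were among the 489 with the same direction. It was 801 with array weights and 134 when only the 6 arrays compared were fitted. The call of Fgf18 was lost without any one of the 3 arrays of 2 h and when only the 6 arrays compared were fitted.

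The genes of RA metabolism and the RA receptors moved as a group at every time. Of this list, 7, 10 and 11 of the 18 measured members were higher at 2, 4 and 6 h and 0, 1 and 2 were lower. When adjusted over the list alone, 8, 10 and 11 were higher and 1, 2 and 3 lower. The list stood above the other genes, with adjusted p = 3.12e-08, 3.93e-05 and 4.85e-05 by camera, and adjusted p = 0.0142, 0.0805 and 0.0919 with an estimated correlation. The 2 h shift of this list was the only list shift against no RA that passed with the estimated correlation. Beside Cyp26a1, the nuclear receptor corepressor Nrip1 rose by 2.18 ± 0.13, 2.51 ± 0.13 and 2.35 ± 0.13 (SE) at 2, 4 and 6 h, the receptor Rarb by 1.88 ± 0.16, 2.16 ± 0.16 and 1.73 ± 0.16, and the retinaldehyde reductase Dhrs3 by 2.07 ± 0.28 and 2.14 ± 0.28 at 4 and 6 h. The receptors Rara and Rarg also rose at 2 h, by 1.02 ± 0.088 and 0.78 ± 0.10. When only the 6 arrays of no RA and 2 h were fitted, the 2 h call of Dhrs3 ended. Untreated values of Rarb lay under the median of all values.

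**Figure D1:**
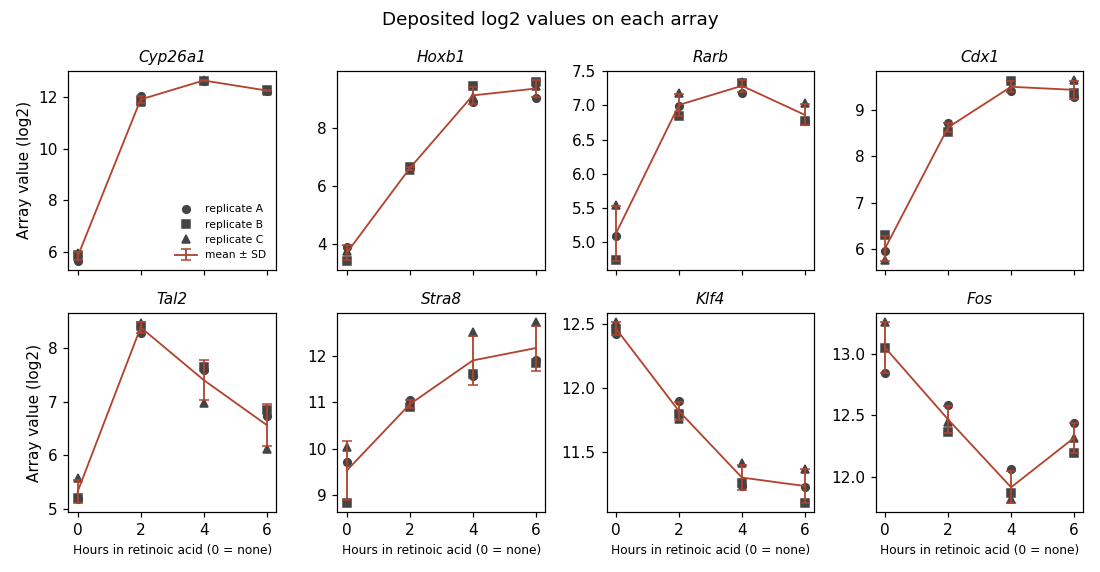
Deposited log2 value (y axis, a different range in each panel) of 8 genes against hours in RA (x axis, 0 for no RA), with a symbol for each replicate and a line through the group means with SD bars, n = 3. Cyp26a1 reached 11.92 ± 0.13 at 2 h from 5.81 ± 0.16 without RA, Tal2 peaked at 2 h, and Klf4 was lower at each RA time than on any untreated array.

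Hox genes of the Hoxa and Hoxb clusters rose, and no measured member of either was called lower. In the Hoxb cluster, 2, 5 and 5 of the 9 measured members were higher at 2, 4 and 6 h and 0, 0 and 0 were lower. The counts adjusted over the list alone were 4, 6 and 6 higher and 0, 0 and 0 lower. Hoxb1 rose by 2.93 ± 0.17, 5.45 ± 0.17 and 5.69 ± 0.17 (SE), Hoxb5 by 2.44 ± 0.23 and 2.73 ± 0.23 at 4 and 6 h after 0.95 ± 0.23 at 2 h, which did not pass, and Hoxb2 by 2.12 ± 0.25 and 2.20 ± 0.25 at 4 and 6 h. Hoxb13, from the far end of the cluster, rose as well (0.82 ± 0.11, 1.73 ± 0.11 and 2.12 ± 0.11). In the Hoxa cluster, 1, 5 and 5 of the 9 measured members were higher at 2, 4 and 6 h and 0, 0 and 0 were lower. With p-values adjusted over the list alone, 2, 5 and 6 were higher and 0, 0 and 0 lower. Hoxa5 rose by 2.75 ± 0.33 and 3.04 ± 0.33 at 4 and 6 h and Hoxa4 by 2.51 ± 0.22 and 2.95 ± 0.22, and the Hoxa4 call at 2 h (0.93 ± 0.22) was lost without RA 2 h replicate A, B or C and without untreated replicate A or B. At 4 h the call of Hoxa3 was lost without any 1 of the 5 arrays other than untreated replicate C, and that of Hoxa7 without untreated replicate B or C or RA 4 h replicate C. The Hoxb list gave adjusted p = 2.76e-05, 1.32e-05 and 4.96e-06 by camera, and adjusted p = 0.415, 0.242 and 0.205 with an estimated correlation. For the Hoxa list the values were adjusted p = 0.0246, 0.00438 and 0.00739 by camera, and adjusted p = 0.684, 0.332 and 0.372 with an estimated correlation. The 2 h shift of the Hoxa list was lost without untreated replicate B (adjusted p = 0.0629), and fry gave 0.108. Untreated values of Hoxb1, Hoxb5, Hoxb13, Hoxa4 and Hoxa5 lay under the median of all values.

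Taken by paralogue number across the clusters, groups 1 to 5 shifted up as a list and groups 9 to 13 did not pass. For groups 1 to 5, 2, 8 and 8 of the 13 measured members were higher at 2, 4 and 6 h and 0, 0 and 0 were lower. Calls adjusted over the list alone numbered 5, 9 and 8 higher and 0, 0 and 0 lower, with adjusted p = 0.000378, 8.76e-06 and 4.96e-06 by camera, and adjusted p = 0.504, 0.242 and 0.205 with an estimated correlation. For groups 9 to 13, 1, 1 and 1 of the 14 measured members were higher at 2, 4 and 6 h and 0, 0 and 0 were lower. If adjusted over the list alone, 1, 1 and 1 members were higher and 0, 0 and 0 lower, with adjusted p = 0.0536, 0.199 and 0.447 by camera. Their 2 h value was 0.0458 with median centring and 0.0450 with the dim filter, and the member that rose was Hoxb13. The difference between the 2 paralogue lists was not tested. No listed Hoxc or Hoxd gene was called by limma at any time, out of 7 and 8 measured, over all genes or adjusted over the list alone, with adjusted p = 0.453, 0.786 and 0.794 by camera for Hoxc and adjusted p = 0.453, 0.592 and 0.611 by camera for Hoxd. At an unadjusted p under 0.05, 0, 0 and 0 Hoxc genes and 0, 0 and 1 Hoxd genes passed at 2, 4 and 6 h. The largest Hoxc value at 6 h was that of Hoxc4 (0.24 ± 0.12, SE) and the largest Hoxd value that of Hoxd8 (0.22 ± 0.11). Hoxc8, Hoxc10, Hoxd1, Hoxd8, Hoxd9, Hoxd12 and Hoxd13 lay under the median of all values on every array. Such values were not tested against background, so the lack of a call does not show that these genes did not respond.

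**Figure D2:**
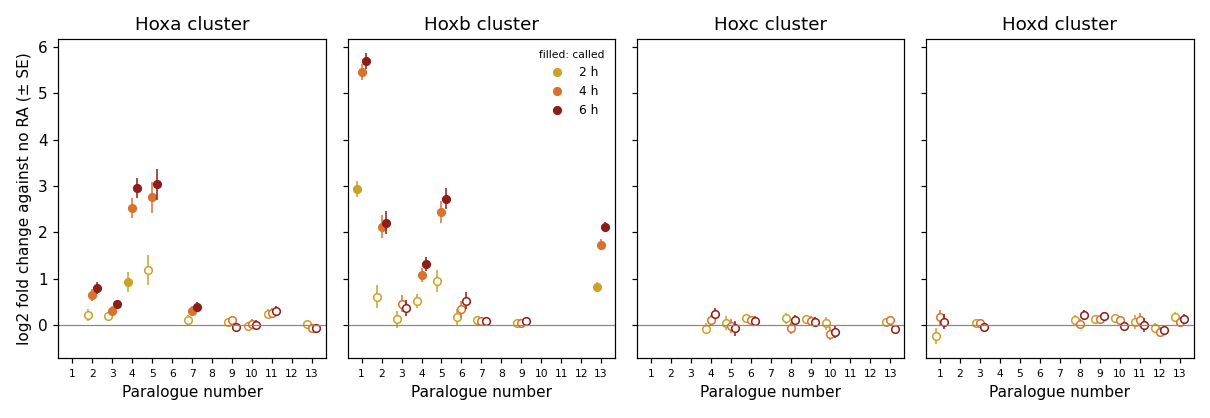
Log2 fold change against no RA (y axis, bars are SE) of each measured Hox gene by its paralogue number (x axis) in the 4 clusters, at 2, 4 and 6 h (colours), with filled symbols for genes called at an adjusted p under 0.05. Hoxb1 reached 5.69 at 6 h, the called Hoxa and Hoxb genes have low numbers except Hoxa7 and Hoxb13, and no listed Hoxc or Hoxd gene was called.

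Among Hox cofactors and Cdx genes the direction was mixed. In this list, 2, 6 and 5 of the 13 measured members were higher at 2, 4 and 6 h and 1, 2 and 5 were lower. Adjusted over the list alone, the numbers were 3, 6 and 6 higher and 2, 2 and 5 lower, with adjusted p = 0.391, 0.162 and 0.269 by camera, while at 2 h its median was -0.0069 and its mean 0.26. Cdx1 rose at every time, by 3.43 ± 0.13 (SE) at 6 h, the TALE homeobox gene Meis2 by 1.12 ± 0.15, 2.59 ± 0.15 and 2.78 ± 0.15, and Meis1 by 0.85 ± 0.16 and 1.11 ± 0.16 at 4 and 6 h. Tgif2, a repressor of TGF-beta responses, fell by 0.35 ± 0.057, 0.58 ± 0.057 and 0.41 ± 0.057. Untreated values of Meis1 and Meis2 lay under the median of all values. With probe sets free of a cross-hybridization suffix, Meis2 had -0.11 at 2 h and Meis1 was not called, and the 2 h call of Tgif2 was lost when only the 6 arrays compared were fitted.

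Regulators of the hindbrain and neural plate changed in both directions. Of them, 3, 7 and 7 of the 22 measured members were higher at 2, 4 and 6 h and 2, 3 and 4 were lower. When adjusted over the list alone, 4, 7 and 8 were higher and 5, 3 and 4 lower, with adjusted p = 0.462, 0.191 and 0.294 by camera. The orphan receptor Nr6a1 rose by 0.75 ± 0.064, 1.68 ± 0.064 and 1.63 ± 0.064 (SE), and Pax6 and Gbx2 rose at 4 h by 1.73 ± 0.21 and 1.74 ± 0.23. Sox11 fell by 0.79 ± 0.092 at 4 h and 0.72 ± 0.092 at 6 h, and Egr2 by 1.35 ± 0.17 at 6 h. Neurogenesis genes shifted down as a list. There, 0, 2 and 1 of the 19 measured members were higher at 2, 4 and 6 h and 2, 7 and 7 were lower. The counts adjusted over the list alone were 1, 2 and 1 higher and 5, 8 and 8 lower, with adjusted p = 0.0133, 0.0357 and 0.0422 by camera, and adjusted p = 0.175, 0.242 and 0.205 with an estimated correlation. The 4 h shift was lost without untreated replicate A (adjusted p = 0.0733). The 6 h shift was lost without A or C (0.0604 and 0.0575) and with the replicate letter as a block (0.0561). Map2, a dendritic microtubule protein, fell by 1.02 ± 0.11 and 1.23 ± 0.11 at 4 and 6 h, Olig2 by 1.29 ± 0.12, 1.03 ± 0.12 and 1.11 ± 0.12, and the Notch ligand Dll1 by 1.18 ± 0.13 and 0.60 ± 0.13. Gadd45g rose by 0.62 ± 0.077 at 6 h. The values of Map2 at 4 and 6 h lay under the median of all values.

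Pluripotency genes moved in both directions. Pou5f1 did not pass at any time (-0.0052 ± 0.053, 0.038 ± 0.053 and 0.089 ± 0.053, SE). Nanog rose by 0.48 ± 0.077 at 2 h and was at 0.21 ± 0.077 and 0.10 ± 0.077 at 4 and 6 h. Sox2 fell by 0.35 ± 0.071 and 0.45 ± 0.071 at 4 and 6 h, Zfp42 by 0.50 ± 0.11 and 0.56 ± 0.11, and Klf4 by 0.64 ± 0.079, 1.16 ± 0.079 and 1.23 ± 0.079. Fgf4 fell by 1.30 ± 0.10 and 1.33 ± 0.10, while Dppa2 rose by 1.08 ± 0.11, 1.80 ± 0.11 and 1.77 ± 0.11. Of the naive pluripotency genes, 3, 5 and 5 of the 24 measured members were higher at 2, 4 and 6 h and 1, 8 and 12 were lower. With p-values adjusted over the list alone, 3, 6 and 5 were higher and 1, 10 and 12 lower, with adjusted p = 0.84, 0.174 and 0.0379 by camera, and adjusted p = 0.954, 0.609 and 0.501 with an estimated correlation, and at 2 h the median was -0.0063 and the mean 0.069. The 6 h shift was lost without untreated replicate A (adjusted p = 0.0873), without B (0.076) and with the dim filter (0.0603), and was 0.00597 without C. In the primed epiblast list, 1, 3 and 3 of the 14 measured members were higher at 2, 4 and 6 h and 1, 3 and 4 were lower. Calls adjusted over the list alone numbered 1, 3 and 3 higher and 5, 3 and 5 lower, with adjusted p = 0.28, 0.786 and 0.473 by camera. The DNA methyltransferase Dnmt3a rose by 1.60 ± 0.089 at 6 h on its brightest probe set, with its probe sets called in both directions, and Otx2 fell by 1.23 ± 0.18, and this list's 2 h value was adjusted p = 0.425, 0.619 and 0.0193 without untreated replicate A, B or C.

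At 4 h the response was broader, with 2332 genes higher and 2561 lower (limma), of which 132 and 127 differed by at least 2-fold. The largest rises were again Cyp26a1 (6.85 ± 0.084 (SE, adjusted p = 2.58e-13)) and Hoxb1 (5.45 ± 0.17), followed by the milk protein gene Csn3 (3.63 ± 0.14), Cdx1 (3.49 ± 0.13), Chac1 (3.12 ± 0.17), Aqp3 (2.86 ± 0.087), Hoxa5 and Meis2. Untreated values of Cyp26a1, Hoxb1, Hoxa5 and Meis2 lay under the median of all values. The largest falls were those of the fucosyltransferase Fut9 (by 2.21 ± 0.10), Mipol1, Lrrc31 (by 1.87 ± 0.24), the growth factor Pdgfc (by 1.84 ± 0.19), Osbpl10 (by 1.76 ± 0.13) and Id2, an inhibitor of helix-loop-helix factors (by 1.72 ± 0.21). Zc3h6 and Zmat4 were next, the 4 h values of Lrrc31 and Zc3h6 lay under the median of all values, and untreated values of Zc3h6 had an SD of 1.02. Of the 4893 genes, 4756 had no overlap between the groups' arrays, against 37.0% of all genes and 10% by chance. When only the 6 arrays of the comparison were fitted, 3081 genes were called.

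At 6 h 2734 genes were higher and 2675 lower, and 166 and 159 of them differed by at least 2-fold. Cyp26a1 (6.46 ± 0.084 (SE, adjusted p = 5.14e-13)), Hoxb1, Csn3 (3.68 ± 0.14), Cdx1, Chac1 (3.14 ± 0.17), Hoxa5, Hoxa4 and Dleu7 (2.87 ± 0.36) rose most, and untreated values of Cyp26a1, Hoxb1, Hoxa5 and Hoxa4 lay under the median of all values. Pdgfc fell by 2.49 ± 0.19, a 5.62-fold decrease, Fry, a large scaffold protein, by 2.25 ± 0.067, Fut9 by 2.20 ± 0.10, Lrrc31 by 2.20 ± 0.24, the guanine nucleotide exchange factor Mcf2 by 2.01 ± 0.06 and Ly6g6e by 1.98 ± 0.18, with Mipol1 and Zmat4 next. The 6 h values of Fry, Lrrc31 and Mcf2 lay under that median. Among the 5409 genes, 5232 had no overlap between arrays, against 39.0% of all genes. The split was 2688 higher and 2712 lower after quantile normalization, and 2641 and 2770 with median centring. Without untreated replicate C 6152 genes were called.

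**Figure D3:**
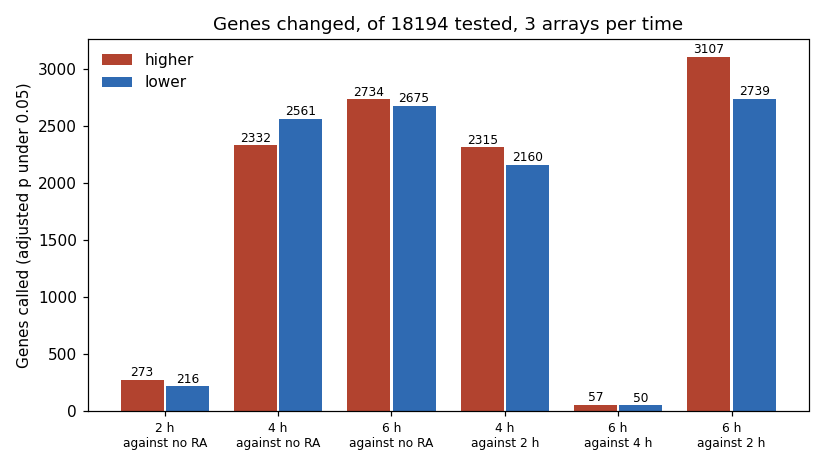
Number of genes called higher or lower (y axis) in each of the 6 comparisons (x axis), of 18194 genes tested with 3 arrays per time. The 2 h arrays gave 273 and 216 genes against no RA, the 4 h arrays 2332 and 2561, and 6 h against 4 h gave 57 and 50.

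Genes of cholesterol synthesis fell at 4 and 6 h. Here 0, 0 and 0 of the 16 measured members were higher at 2, 4 and 6 h and 0, 9 and 11 were lower. If adjusted over the list alone, 0, 0 and 0 members were higher and 0, 9 and 11 lower, with adjusted p = 0.00181, 0.000106 and 4.96e-06 by camera, and adjusted p = 0.504, 0.242 and 0.205 with an estimated correlation, and 4 members had an unadjusted limma p under 0.05 at 2 h. The 2 h shift of this list was lost without untreated replicate A (adjusted p = 0.0766), and fry gave 0.0508. The sterol sensor Insig1 fell by 0.91 ± 0.081 and 1.13 ± 0.081 (SE) at 4 and 6 h, the demethylase Msmo1 by 0.75 ± 0.056 and 0.83 ± 0.056, the squalene epoxidase Sqle by 0.61 ± 0.086 and 0.77 ± 0.086, and the regulator Srebf2 by 0.46 ± 0.073 and 0.66 ± 0.073. The list of immediate early genes, which respond to serum and growth factors, shifted down. Of these, 1, 1 and 1 of the 22 measured members were higher at 2, 4 and 6 h and 3, 8 and 10 were lower. Adjusted over the list alone, the numbers were 1, 1 and 1 higher and 8, 8 and 11 lower, with adjusted p = 0.0385, 0.00438 and 0.0126 by camera, and adjusted p = 0.687, 0.452 and 0.509 with an estimated correlation. Fos fell by 0.58 ± 0.11, 1.14 ± 0.11 and 0.73 ± 0.11, Jun by 1.00 ± 0.14, 1.47 ± 0.14 and 0.72 ± 0.14 and Egr1 by 0.73 ± 0.10, 1.13 ± 0.10 and 1.30 ± 0.10, while the stress factor Atf3 rose by 0.93 ± 0.12 at 2 h. The Fos call at 2 h was lost without RA 2 h replicate B or C and when only the 6 arrays compared were fitted, and the Msmo1 call at 4 h with probe sets free of a cross-hybridization suffix. The shift of immediate early genes was lost at every time without untreated replicate B (adjusted p = 0.75, 0.0938 and 0.131). At 2 h it was also lost without A (0.057) and with the dim filter (0.215), and fry gave 0.343. Without C, in which feeder markers were lower, the values were 4.98e-06, 1.63e-05 and 8.65e-05, with 5, 12 and 14 members lower. Targets of LIF and STAT3 signalling gave a downward shift at 4 and 6 h that depended on the setting. In that list, 1, 3 and 3 of the 15 measured members were higher at 2, 4 and 6 h and 3, 6 and 7 were lower. When adjusted over the list alone, 1, 3 and 3 were higher and 4, 6 and 7 lower, with adjusted p = 0.0735, 0.0472 and 0.0422 by camera, and adjusted p = 0.687, 0.452 and 0.503 with an estimated correlation. Both calls were lost without untreated replicate A (adjusted p = 0.193 and 0.156), without B (0.174 and 0.131), with median centring (0.0687 and 0.0538) and with the dim filter (0.0891 and 0.0725). Without C the values were 0.00028, 0.00249 and 0.00261 at 2, 4 and 6 h. Il6st, the shared receptor subunit of this pathway, fell by 0.68 ± 0.076 and 0.85 ± 0.076, and the kinase gene Pim1 rose by 0.69 ± 0.092, 1.00 ± 0.092 and 0.92 ± 0.092. For Stat3 itself, a probe set other than the brightest was higher at 6 h while the brightest fell (by 0.34 ± 0.084), and the 6 h call was lost with the mean of probe sets and when only the 6 arrays compared were fitted.

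The list of unfolded protein and amino acid stress genes shifted up at every time. Of them, 5, 7 and 8 of the 18 measured members were higher at 2, 4 and 6 h and 0, 1 and 1 were lower. The counts adjusted over the list alone were 6, 7 and 10 higher and 0, 2 and 1 lower, with adjusted p = 0.000106, 0.0026 and 9.93e-05 by camera, and adjusted p = 0.34, 0.298 and 0.205 with an estimated correlation. Beside Chac1, the pseudokinase Trib3 rose by 1.10 ± 0.081, 1.17 ± 0.081 and 1.59 ± 0.081 (SE), the ER-associated degradation factor Herpud1 by 1.55 ± 0.10, 1.43 ± 0.10 and 1.40 ± 0.10, and Atf4, the transcription factor that activates Chac1 and Trib3, by 0.49 ± 0.073, 0.36 ± 0.073 and 0.55 ± 0.073. The 2 h call of Atf4 was lost when only the 6 arrays compared were fitted.

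The list of primitive streak and mesoderm genes shifted up at 4 and 6 h, while most members were not called. In this list, 0, 5 and 6 of the 18 measured members were higher at 2, 4 and 6 h and 0, 1 and 1 were lower. With p-values adjusted over the list alone, 1, 5 and 6 were higher and 1, 1 and 1 lower, with adjusted p = 0.377, 0.0117 and 0.0225 by camera, and adjusted p = 0.687, 0.238 and 0.205 with an estimated correlation. The 6 h shift was lost with the dim filter (adjusted p = 0.0632). Tcf15, a paraxial mesoderm factor, rose by 1.22 ± 0.13 and 1.21 ± 0.13, Wnt8a by 1.61 ± 0.19 at 4 h, Wnt3a by 0.89 ± 0.13 and 1.21 ± 0.13, and Gsc by 0.81 ± 0.091 and 0.83 ± 0.091, while Fgf8 fell by 0.77 ± 0.17 at 4 h. Gsc on every array, Wnt8a and Wnt3a on the untreated arrays and Fgf8 at 4 h lay under the median of all values. Targets of p53 moved up as a list at 2 and 4 h and not at 6 h, where the median was -0.018 and the mean 0.0021. Here 1, 8 and 3 of the 16 measured members were higher at 2, 4 and 6 h and 0, 0 and 2 were lower. Calls adjusted over the list alone numbered 2, 11 and 3 higher and 1, 0 and 2 lower, with adjusted p = 0.0385, 0.000452 and 0.947 by camera, and adjusted p = 0.687, 0.332 and 0.977 with an estimated correlation. The 2 h shift was lost without untreated replicate A or C (adjusted p = 0.057 and 0.142), and fry gave 0.242. Aen and Ccng1 rose by 0.57 ± 0.091 and 0.46 ± 0.10 at 4 h, and at 6 h Bbc3 fell by 0.52 ± 0.083. Mitotic genes shifted down as a list at 4 h. Of those, 0, 0 and 1 of the 21 measured members were higher at 2, 4 and 6 h and 0, 11 and 8 were lower. If adjusted over the list alone, 0, 0 and 1 members were higher and 0, 11 and 9 lower, with adjusted p = 0.453, 0.00271 and 0.0891 by camera, and adjusted p = 0.823, 0.452 and 0.686 with an estimated correlation. The 6 h value was 0.0166 without untreated replicate A, fry gave 0.0241, and Bub1b fell by 0.46 ± 0.076 and 0.45 ± 0.076 at 4 and 6 h. Hmmr fell by 0.41 ± 0.084 at 4 h on its brightest probe set and not on its probe set without a cross-hybridization suffix.

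**Figure D4:**
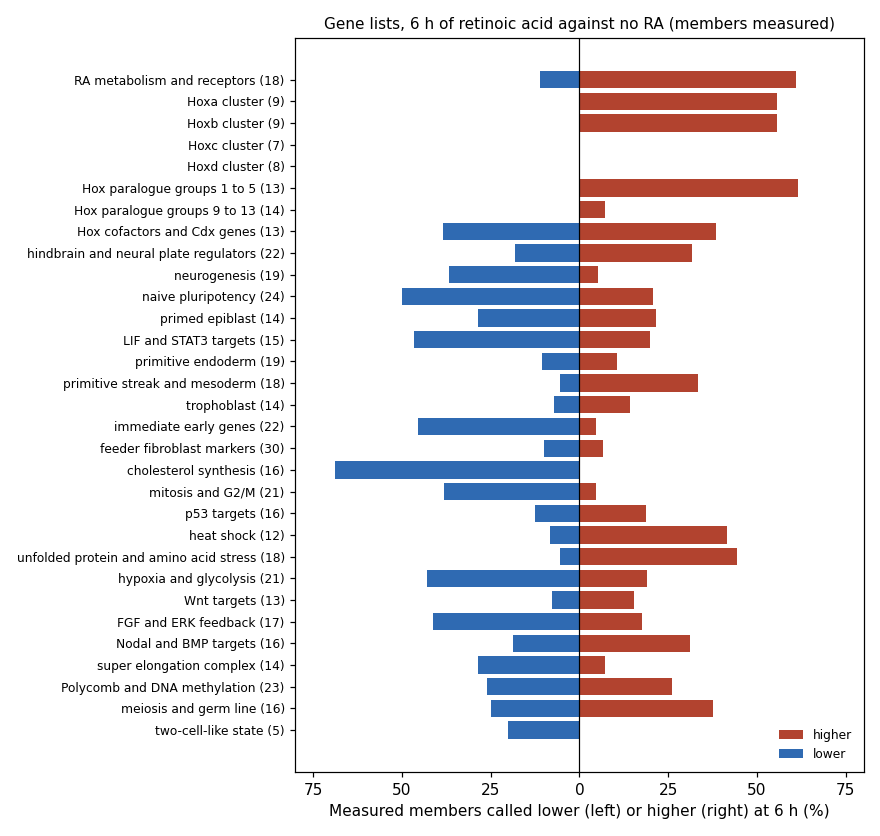
Percentage of the measured members of each of the 31 gene lists (y axis, members measured in brackets) called higher (right) or lower (left) at 6 h against no RA (x axis). In cholesterol synthesis 11 of 16 members were lower and none higher, and in RA metabolism and receptors 11 of 18 were higher.

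The next comparisons asked which genes moved between RA times. Between 2 and 4 h 2315 genes rose and 2160 fell, 67 and 75 of them by at least 2-fold, and between 4 and 6 h 57 rose and 50 fell. The balance depended on scaling. After quantile normalization 2120 rose and 2327 fell from 2 to 4 h, and 50 and 58 from 4 to 6 h. With median centring the numbers were 2148 and 2340, and 78 and 47. Hoxb1 rose by 2.52 ± 0.17 (SE, adjusted p = 5.93e-06) from 2 to 4 h, followed by the germ cell regulator Prdm14 (1.70 ± 0.34), the splicing kinase Clk2 (1.70 ± 0.25), Hs3st3b1 (1.65 ± 0.11) and Gbx2 (1.58 ± 0.23). Fut9 (by 1.85 ± 0.10), the stress gene Ndrg1 (by 1.81 ± 0.11), Mipol1, Ly6g6e and Osbpl10 fell most. From 4 to 6 h the amino acid stress gene Pck2 (0.78 ± 0.12), Jun (0.75 ± 0.14) and Vsir (0.74 ± 0.11) rose, with Plekha2 and Phf21a, and Fry (by 1.18 ± 0.067 (SE, adjusted p = 1.31e-05)), Cidea (by 1.09 ± 0.14), Jam2, St6galnac3 and Slc19a2 fell. The count for this last step was 5, 14 or 9 without RA 4 h replicate A, B or C and 14, 11 or 20 without RA 6 h replicate A, B or C, and between 36 with the mean of a gene's probe sets and 696 with array weights in other settings that kept the threshold. From 2 to 6 h 3107 genes rose and 2739 fell, led by Hoxb1, Zfp423 (2.15 ± 0.12), Hoxa4, Hoxa5 and Clk2, and by Fry (by 2.29 ± 0.067), Ly6g6e, Pdgfc, Cidea and Lrrc31. After quantile normalization the split from 2 to 6 h was 2789 higher and 2918 lower, and with median centring 3025 and 2923. Of the genes in this paragraph, Fry and Lrrc31 at 6 h, St6galnac3 at 4 and 6 h and Hoxa4 at 2 h lay under the median of all values on all 3 arrays.

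Calls were also compared across times. Of the 489 genes called at 2 h, 321 were called in the same direction at 4 h and 20 in the opposite one, and 268 and 43 at 6 h. At 4 and 6 h 3922 genes were shared in direction and 1 was opposed. Unchanged groups simulated against the shared untreated arrays gave at most 1 shared gene in 100 simulations. Such groups yield almost no calls, so this value does not say what lists as long as these would share. Independent lists would share 35.0 higher and 30.4 lower genes at 2 and 4 h, 41.0 and 31.8 at 2 and 6 h, and 350 and 377 at 4 and 6 h, where 201 and 120, 181 and 87, and 1931 and 1991 were seen. The 3 untreated arrays are too few to be split, so part of the excess may come from the shared controls. Shared calls numbered 500 at 2 and 4 h and 459 at 2 and 6 h without untreated replicate C. Without RA 2 h replicate A, B or C they numbered 167, 166 or 186 at 2 and 4 h and 144, 142 or 162 at 2 and 6 h. Of the 43 opposed genes, 15, 26 or 29 kept opposite calls without untreated replicate A, B or C, and 16, 13 or 11 without RA 2 h replicate A, B or C. Returning genes numbered 72 that rose and 78 that fell at 2 h, were not called at 6 h and changed back between 2 and 6 h. Tal2 stayed called but fell by 1.82 ± 0.20 from 2 to 6 h. A further 2114 higher and 2438 lower genes were first called at 4 h, of which 1738 and 1905 kept their direction and call at 6 h. The limma F test over the time course called 6597 genes, 36.3% of those tested.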

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

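Of the tests in this part, those on the step between 2 and 4 h and on untreated replicate C were chosen after the results were seen, and those on splits of the arrays and on genes with opposite directions were planned. The gap test for single samples was not applied to groups of 3 arrays.

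Effects at 2 and 6 h differed in direction for 43 genes, each called against no RA both times and called between 2 and 6 h. Of these, 10 were higher at 2 h and lower at 6 h and 33 the reverse. Bcl3 differed by 1.13 between 6 and 2 h and Hs3st3b1 by 1.53. The 2 h call of Bcl3 was lost without untreated replicate A or C and without RA 2 h replicate A, B or C. It was also lost with quantile normalization, every probe set, a fit of only the groups compared and the replicate letter as a block. The 6 h call of Hs3st3b1 was lost without RA 6 h replicate A and with the mean of its probe sets. Without untreated replicate C, 29 of the 43 were still called in opposite directions, which argues against that array as the whole cause. The number still called was 15 or 26 without untreated replicate A or B and 16, 13 or 11 without RA 2 h replicate A, B or C. An early response that turns over by 6 h stays open as a hypothesis, as does the medium change, which the design gives together with RA.

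Untreated replicate C lay apart from A and B. A smaller share of feeder cells in it may account for part of this: the feeder markers had a median of -0.50 in C relative to A and B, below all 10000 lists of genes matched on level, and 24 of 30 were lower. For the 68 genes at least 2-fold higher in C, the pluripotency genes argue against it. These would rise with the share of stem cells and had a median of -0.074. The standard error of that median, 0.103, came from resampling the genes and does not measure the spread between arrays. Poor labelling of that array cannot be told apart from other causes, because the 1 array with lower labelling controls, RA 6 h replicate C, had a standard deviation from its group of 0.106 and 1 array decides nothing. Some genes that changed in RA also differed in C from A and B. Of the largest rises at 2 h, Camk2n1 (1.40), Chac1 (0.65), Cidea (0.56), Tal2 (0.38), Cyp26a1 (0.20) and Hoxb1 (0.10) were higher in C. Aqp3 (-0.14) and Cdx1 (-0.37) were lower. Of the largest falls at 4 h, Zmat4 (-1.30), Id2 (-0.97) and Pdgfc (-0.82) were lower in C. Zc3h6 (1.69), Lrrc31 (0.44), Osbpl10 (0.44), Mipol1 (0.24) and Fut9 (0.15) were higher. Such genes were not tested as a set in C. The design names no difference between the untreated replicates, and no other explanation was tested.

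The step between 2 and 4 h called 4475 genes. The feeder markers did not move as a set, which argues against a change in the share of feeder cells. Their median moved by 0.0058, and of 30 markers 2 were called higher and 2 lower. The standard error of that median, 0.0686, came from resampling the genes and does not measure the spread between arrays. The called genes had a median size of 0.39, but they were picked for their change, so the values are not of like kind. A programme that also varied among untreated cultures cannot be told apart: deviations of untreated replicates A, B and C, each from the mean of the other untreated arrays, correlated with the step by 0.124, -0.196 and 0.0526, too weakly to name it and too strongly in A and B to exclude it. A labelling difference between the arrays cannot be told apart, since the labelling controls differed by 0.13 and their range within a group reached 0.713, which leaves open a difference that spares the controls. A response to RA or to the medium stays open.

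Signal was also present in the 9160 probe sets with no gene name, which the comparisons did not use. Of them, 193 were called at 2 h, 630 at 4 h and 596 at 6 h, that is 2.11%, 6.88% and 6.51%. Among named genes the shares were 2.69%, 26.9% and 29.7%. These are shares of unlike units: all unnamed probe sets were counted and adjusted among themselves, while each named gene had its brightest probe set. At 2 h, 36 of the unnamed calls were higher and 157 lower.

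Other splits of the same arrays were run for each comparison. Of the 10 splits of the 6 arrays, 1, the real one, called as many genes as the real count at 2 h (489, highest other 1), at 4 h (4893, highest other 0), at 6 h (5409, highest other 0), from 2 to 4 h (4475, highest other 0), from 4 to 6 h (107, highest other 0) and from 2 to 6 h (5846, highest other 0), and 10 splits are too few for a share under 0.05. For the F test over the time course, 1 of 100 groupings of the 12 arrays called as many as 6597 genes. It was the real one, and the highest other called 37, which argues against chance assignment of arrays to groups for that count. The labels do not say whether replicates were separate cultures, so this test does not cover chance differences between cultures.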

How the results depend on the processing

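Leaving out arrays in the overlap of calls, and leaving out each untreated array for the lists, were chosen after the results were seen. A group left with 2 arrays is fitted with the spread of all groups. The cause of the changes below was not tested unless stated. Leaving out 1 array gave 219 to 734 genes at 2 h, 3789 to 5299 at 4 h, 4328 to 6152 at 6 h, 3052 to 3396 from 2 to 4 h, 5 to 20 from 4 to 6 h, 4469 to 5039 from 2 to 6 h and 5506 to 7805 by the F test. Shared calls ranged from 166 to 500 for 2 and 4 h, 142 to 459 for 2 and 6 h and 3137 to 4375 for 4 and 6 h. From 4 to 6 h the count was 36 with the mean of probe sets, 244 with the dim filter (12039 genes), 207 with trend and robust, 696 with array weights, 251 with only those groups, 7 at an adjusted p under 0.01 and 2 at 2-fold or more. At 2 h it was 801 with array weights, in which untreated replicate C weighed 0.177, and 134 with only those groups, and at 4 h 3081 with only those groups. An adjusted p under 0.01, stricter by construction, gave 195, 2994 and 3479 genes at 2, 4 and 6 h, 2364 from 2 to 4 h, 3619 from 2 to 6 h, 4174 by the F test and 136, 123 and 2357 shared calls, and at least 2-fold gave 50, 259, 325, 142 and 259. Stat3 at 6 h was called in the opposite direction with every probe set (0.64, adjusted p = 0.00654). Other calls were lost with estimates of the opposite sign: Cbx7 at 6 h with the mean of probe sets (0.024, adjusted p = 0.832), and with unsuffixed probe sets Hmmr at 4 h (0.11, adjusted p = 0.535) and 6 h (0.24, adjusted p = 0.133) and Meis2 at 2 h (-0.11, adjusted p = 0.737). Of 38 list shifts called, 1 passed with an estimated correlation, 30 with the dim filter, 35 with median centring and 36 with the replicate block. The dim filter ended those of immediate early genes at 2 h, LIF and STAT3 targets and feeder markers at 4 h, and naive pluripotency, LIF and STAT3 targets, primitive streak, heat shock and hypoxia at 6 h. Median centring ended those of LIF and STAT3 targets at 4 and 6 h and hypoxia at 6 h. A different question was asked with fry: whether the members of a list moved in a common direction, against no change. This test passed 32 of the 38. It did not pass Hoxa, immediate early genes, feeder markers, cholesterol synthesis and p53 targets at 2 h and feeder markers at 4 h. It passed 18 others, among Hox cofactors, hindbrain regulators, Wnt and Nodal and BMP targets at every time, the super elongation complex at 4 and 6 h, naive pluripotency at 4 h, and mitosis, FGF and ERK feedback and Polycomb at 6 h. With the replicate letter as a block the counts were 432, 4909, 5386, 4422, 83 and 5838, and 6449 by the F test, and neurogenesis (adjusted p = 0.0561) and hypoxia (0.0526) at 6 h were not called. Pairing by letter was weak at most: 18 same-letter correlations between deviations ran from -0.128 to 0.315, and 4 were over 0.1. Their mean was 0.037, and 5 of 12 arrays were best matched by their own letter. The mean for other letters was -0.018. Deviations from a group mean cancel within the group, so that value follows nearly from the same-letter mean and is no independent reference. A culture or batch shared by a letter was not excluded.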

Other observations

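In this part the tests of Hox order and the level-matched check of neighbouring genes were chosen after the results were seen. Heat shock genes shifted up at 4 and 6 h: 0, 5 and 5 of the 12 measured members were higher at 2, 4 and 6 h and 0, 0 and 1 were lower. Adjusted over the list alone, the numbers were 0, 6 and 6 higher and 0, 1 and 1 lower, with adjusted p = 0.979, 0.0072 and 0.0225 by camera, and adjusted p = 0.985, 0.242 and 0.289 with an estimated correlation. The 6 h shift was lost without untreated replicate C (adjusted p = 0.0575) and with the dim filter (0.0603). At 2 h the test pointed up while the median was -0.01. Hspa1b rose by 0.85 ± 0.087 (SE) and Hsph1 by 0.63 ± 0.12 at 4 h. Hypoxia and glycolysis genes shifted down at 4 and 6 h: 1, 3 and 4 of the 21 measured members were higher at 2, 4 and 6 h and 1, 10 and 9 were lower. When adjusted over the list alone, 1, 3 and 5 were higher and 1, 11 and 10 lower, with adjusted p = 0.575, 0.00387 and 0.0463 by camera, and adjusted p = 0.935, 0.526 and 0.686 with an estimated correlation. The 6 h shift was lost without untreated replicate C (adjusted p = 0.275), with median centring (0.0512), with the dim filter (0.0627) and with the replicate letter as a block (0.0526). Ndrg1 fell by 1.68 ± 0.11 and the mitophagy receptor Bnip3 by 1.00 ± 0.09 at 4 h, while the angiogenic factor Vegfa rose by 1.40 ± 0.18. The FGF and ERK feedback list did not pass: 1, 3 and 3 of the 17 measured members were higher at 2, 4 and 6 h and 3, 6 and 7 were lower. The counts adjusted over the list alone were 1, 3 and 3 higher and 6, 6 and 7 lower, with adjusted p = 0.232, 0.199 and 0.115 by camera. Without untreated replicate C that list passed at each time (adjusted p = 0.000143, 0.00356 and 0.000796), and without A (0.639, 0.566 and 0.423) or B (0.65, 0.511 and 0.31) at none. The fry test, against no change, gave 0.0319 at 6 h. Fgf15 fell by 1.32 ± 0.10 and Etv4 rose by 1.14 ± 0.11 at 4 h.

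The remaining lists did not shift by camera either, while fry, which tests against no change, passed some of them (Wnt targets and Nodal and BMP targets at every time, the super elongation complex at 4 and 6 h and Polycomb at 6 h). Among Wnt targets, 2, 2 and 2 of the 13 measured members were higher at 2, 4 and 6 h and 0, 1 and 1 were lower. With p-values adjusted over the list alone, 2, 2 and 1 were higher and 0, 1 and 1 lower, with adjusted p = 0.453, 0.592 and 0.559 by camera, and Lef1 fell by 0.80 ± 0.13 at 4 h. Among Nodal and BMP targets, 3, 2 and 5 of the 16 measured members were higher at 2, 4 and 6 h and 3, 5 and 3 were lower. Calls adjusted over the list alone numbered 5, 6 and 5 higher and 4, 5 and 3 lower, with adjusted p = 0.495, 0.592 and 0.359 by camera, and Bmp4 rose by 1.39 ± 0.13 at 4 h while Id4 fell by 0.90 ± 0.13. For the super elongation complex, 0, 1 and 1 of the 14 measured members were higher at 2, 4 and 6 h and 1, 4 and 4 were lower. If adjusted over the list alone, 0, 1 and 1 members were higher and 1, 4 and 4 lower, with adjusted p = 0.516, 0.199 and 0.308 by camera, medians of 0.0059 and 0.038 and means of -0.22 and -0.23 at 4 and 6 h, and Aff3 fell by 1.10 ± 0.10. For Polycomb and DNA methylation, 2, 5 and 6 of the 23 measured members were higher at 2, 4 and 6 h and 1, 6 and 6 were lower. Adjusted over the list alone, the numbers were 4, 5 and 6 higher and 3, 7 and 7 lower, with adjusted p = 0.716, 0.786 and 0.794 by camera, a median of -0.019 and a mean of 0.0059 at 2 h, and the demethylase gene Kdm6b rose by 0.81 ± 0.065 at 6 h. In meiosis and germ line, 1, 2 and 6 of the 16 measured members were higher at 2, 4 and 6 h and 1, 3 and 4 were lower. When adjusted over the list alone, 1, 4 and 7 were higher and 1, 3 and 4 lower, with adjusted p = 0.453, 0.592 and 0.476 by camera, and Stra8, a gene needed for meiosis, rose by 2.38 ± 0.33 and 2.64 ± 0.33 at 4 and 6 h. In the two-cell-like state list, 0, 0 and 0 of the 5 measured members were higher at 2, 4 and 6 h and 0, 1 and 1 were lower. The counts adjusted over the list alone were 0, 0 and 0 higher and 0, 1 and 1 lower, with adjusted p = 0.979, 0.592 and 0.447 by camera. Tdpoz1, the member called at 6 h, lay under the median of all values on every array. Its 6 h call was lost in 8 settings, among them leaving out untreated replicate A or C or RA 6 h replicate A or C. For primitive endoderm, 0, 1 and 2 of the 19 measured members were higher at 2, 4 and 6 h and 1, 2 and 2 were lower. With p-values adjusted over the list alone, 0, 1 and 2 were higher and 1, 2 and 2 lower, with adjusted p = 0.877, 0.786 and 0.559 by camera, a median of -0.028 and a mean of 0.0026 at 6 h, and Gata6 rose by 0.79 ± 0.10 and 0.81 ± 0.10 at 4 and 6 h. For trophoblast, 1, 3 and 2 of the 14 measured members were higher at 2, 4 and 6 h and 0, 1 and 1 were lower. Calls adjusted over the list alone numbered 1, 3 and 2 higher and 0, 1 and 1 lower, with adjusted p = 0.544, 0.305 and 0.359 by camera, and Eomes rose by 0.78 ± 0.088 at 6 h while the keratin gene Krt19 fell by 0.83 ± 0.11.

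A hypothesis was that Hox genes with low paralogue numbers rose more. In the Hoxa cluster the Spearman correlation of number with the 6 h change was -0.783 over 9 genes (exact p = 0.0172), and over all 12 relations tested the adjusted p was 0.153, so it did not pass over the set. In the Hoxb cluster it was -0.55 (exact p = 0.133). Without Hoxb13, a gene left out after its value was seen, it was -0.762, for which no p-value was computed. In the Hoxc cluster, where no gene was called by limma, it was -0.714 over 7 genes (exact p = 0.0881), and in the Hoxd cluster -0.167 (exact p = 0.703).

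Another hypothesis was that genes that rose lie next to each other, with Hox genes left out. Genes higher at 2 h formed 10 neighbouring pairs, where permutation gave a mean of 3.87 (permutation p = 0.0052, adjusted p = 0.0104) and permutation matched on level a mean of 4.25 (permutation p = 0.0094). Tal2 with Tmem38b and Camk2n1 with Mul1 are among the pairs, of which Tmem38b and Mul1 were chosen after their values were seen. A regional response may be a candidate explanation, and shared promoters were not tested. For genes at least 2-fold higher at 6 h there were 2 pairs against a mean of 1.27 (permutation p = 0.366).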
